A study of Homo sapiens with 8 samples.

How the data were processed

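Total RNA from KYSE70 cells was sequenced after 72 h with 10 µM pyrimethamine (n = 2) or 20 nM mitoxantrone (n = 3), or untreated (n = 3). RNA was extracted with a column kit and libraries followed Illumina protocols, per the labels. Per the submitters' processing notes, the tools were FastQC 0.11.5, cutadapt 1.12, STAR 2.6.90c and featureCounts 1.5.1 with the human build hg38. The annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here, so paralogs, overlapping genes and antisense genes are named as uncertain.

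The deposited table holds 28281 genes and 8 libraries, 1 column per library, with 0 columns of other samples. Its values are a normalised signal that the authors made by dividing gene counts by size factors, as the deposited table's name states. The values of each library were whole multiples of a single step, so whole reads were recovered. Within a tolerance of 0.1 read, 100% of values came out whole in every library. Recovered totals were 17555689 to 24774358 reads. The step corresponded to a median-ratio size factor within 0.984 to 1.00 of the one recomputed here with DESeq2. Of the genes, 447 were 0 in every library, and 1 row carries a date in place of a symbol, as spreadsheets produce. Gene positions, transcript lengths and GC content came from GENCODE 29 on GRCh38, matched by symbol for 20846 genes and by an older or newer symbol for 654, with 6781 unmatched; 91.4% of tested genes had a length. The genome sequence was not used here.

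The main test was limma 3.58.1 (R 4.3.3) on log2(value + 1), with lmFit and eBayes with a trend, for genes with a mean value of at least 10 over the libraries (15350). A pseudocount of 1 understates changes of low genes. All 8 libraries shared 1 estimate of the spread per gene, with 5 residual degrees of freedom and group as the single term. This assumes the same spread in every group, although the pyrimethamine libraries differed far more than those of the other groups. The 3 comparisons were pyrimethamine minus untreated, mitoxantrone minus untreated and mitoxantrone minus pyrimethamine, each two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. The median standard error over genes was 0.335 log2 units for pyrimethamine and 0.300 for mitoxantrone. Since the values are not raw counts, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on recovered reads served as alternatives. They called 670 and 1738 genes for pyrimethamine, 8478 and 9238 for mitoxantrone and 6713 and 8088 between the compounds, in the order of the tools, beside 553, 8430 and 6299; these are the counts of genes changed by pyrimethamine, genes changed by mitoxantrone and genes differing between mitoxantrone and pyrimethamine.

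Before the data were examined, 36 gene lists were fixed, among them markers of fibroblasts, leukocytes, endothelium and glandular epithelium, and 32 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01, adjusted over 96 tests of lists and comparisons. The calls numbered 18 with pyrimethamine, 15 with mitoxantrone and 8 between the compounds, of which 1, 0 and 0 held with an estimated correlation. With fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes, 16, 23 and 16 lists passed, and 21, 31 and 32 in its test for change in either direction. Lists share members, such as SLC7A11 in the NRF2 and ATF4 lists and CYP4F11 in the NRF2 and P450 lists.

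Genes were named by a rule fixed before the data were examined. It takes NFE2L2, KEAP1, NQO1, GCLM, GCLC, TXNRD1, SLC7A11, AKR1B10, HMOX1, TYMS, TOP2A, TOP2B, CDKN1A and MDM2 in both comparisons with untreated cells. It adds, per comparison with untreated cells, the 6 highest and the 6 lowest log2 fold changes (4 each between the compounds) among called genes with a mean value of at least 100, no overlap between the libraries of the groups and no clone or locus symbol. That mean is over all 8 libraries, so a group outside the comparison can carry a gene past it. It also adds up to 3 members with the smallest adjusted p of each list described. Any other gene is said to be named after its value was seen. Some genes that the rule takes are not reported here.

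The tests were run on simulated data first, with 200 of 15350 genes changed. For pyrimethamine 0%, 1.59% and 60.3% of genes changed 1.5-, 2- and 4-fold were recovered, with 0 false calls. For mitoxantrone it was 2.9%, 6.78% and 73.6%, with 4 false calls, and between the compounds 27.5% with 2. A simulated list moved 1.5-fold with mitoxantrone alone had an adjusted p of 3.99e-16, and 0 unchanged lists were called. Simulated genes varied independently, with the same dispersion in every group, and unchanged lists were random genes. The simulation therefore cannot show how often lists whose members vary together are called falsely. Nor does it cover a wider spread in the pyrimethamine group. With only 200 genes changed, the adjusted threshold is stricter than in the real mitoxantrone comparison, where 8430 genes passed. The recovered shares therefore do not carry over to that comparison.

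Alternatives were pseudocounts of 0.5 and 10, no filter, a mean of at least 50, TMM and upper-quartile scaling, quantile normalisation, robust eBayes, a fit of only the 2 groups compared, edgeR, DESeq2, replicate numbers as a block, and leaving out each library. Adjustment of each library for transcript length and GC content with splines, and cyclic loess, were added after the data were seen. Shared controls were examined with 50 simulations of unchanged groups. Python 3.11.15 was used for annotation and figures. The 13 mitochondrially encoded genes fixed as a list were not analysed here. Replicates were compared for duplication by a chi-square of their reads per degree of freedom, which was 3.54 to 4.47 between untreated libraries, 394 between the pyrimethamine libraries and 4.84 to 13.4 between mitoxantrone libraries.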

Results

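RNA sequencing was carried out on KYSE70, an established cell line of human esophageal squamous cell carcinoma, after exposure to either of 2 compounds named in the series title as inhibitors of NRF2. NRF2, encoded by NFE2L2, is the transcription factor that drives antioxidant and detoxification genes, and KEAP1 is its repressor. Pyrimethamine is an antifolate, and mitoxantrone is an anthracenedione that poisons type II topoisomerases. The groups were untreated cells (n = 3), cells given 10 µM pyrimethamine (n = 2) and cells given 20 nM mitoxantrone (n = 3), with a treatment time of 72 h. The labels do not state whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

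Read totals recovered from the deposited size-factor-normalised values were 20702029, 24774358 and 18176269 in untreated replicates 1 to 3, 23350504 and 19196482 in pyrimethamine replicates 1 and 2, and 17555689, 20908772 and 22400560 in mitoxantrone replicates 1 to 3. Of 28281 genes in the table, 15350 had a mean value of at least 10 and were tested. Across genes, which are not independent replicates, Pearson correlations between libraries were 0.988 to 0.990 within the untreated group and 0.981 to 0.984 within the mitoxantrone group. The pyrimethamine libraries correlated at 0.890 with each other. Replicate 2 of pyrimethamine correlated at 0.953 to 0.967 with the mitoxantrone libraries, and replicate 1 at 0.784 to 0.830. No pair of libraries of a group differed by as little as sampling noise.

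**Figure D1:**
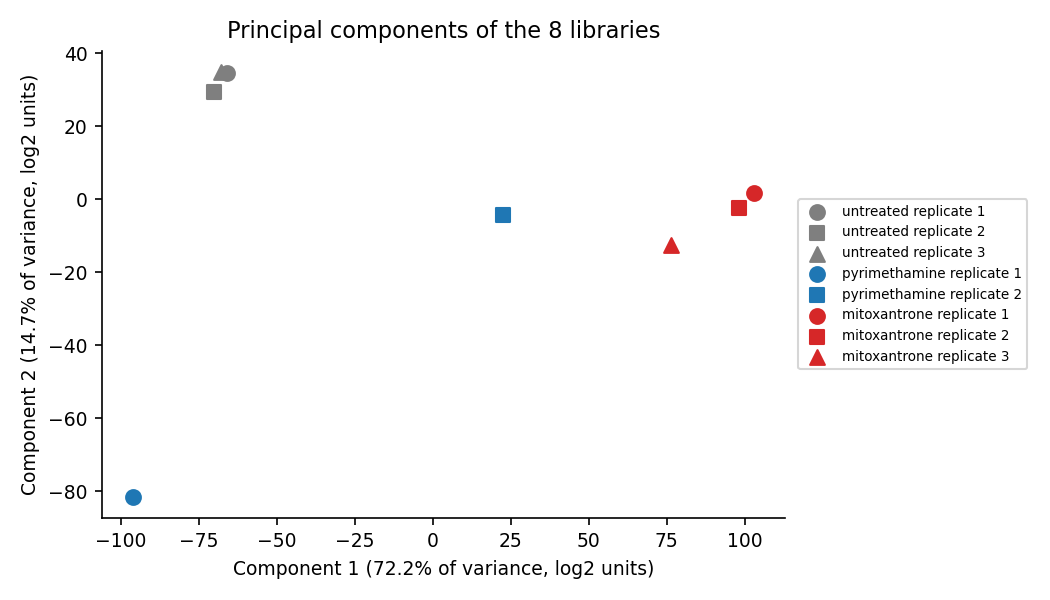
Principal components of log2(value + 1) over the 15350 tested genes, with component 1 (72.2% of variance) on the x axis and component 2 (14.7%) on the y axis, 1 point per library. The untreated and mitoxantrone libraries form separate groups, and the 2 pyrimethamine libraries lie far apart, at 22.5 (replicate 2) and -95.9 (replicate 1) on component 1.

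Cytosolic ribosomal protein genes took 9.73%, 9.81% and 9.60% of reads in the untreated libraries and 16.8%, 17.4% and 15.8% in the mitoxantrone libraries. They took 3.94% in pyrimethamine replicate 1 and 12.1% in replicate 2. Change from the untreated mean also followed transcript length. Over the 14031 tested genes with an annotated length, the rank correlation with length was -0.418, -0.418 and -0.396 in the mitoxantrone libraries, -0.388 in pyrimethamine replicate 2 and 0.343 in pyrimethamine replicate 1, beside -0.122 to 0.0647 in the untreated libraries.

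**Figure D2:**
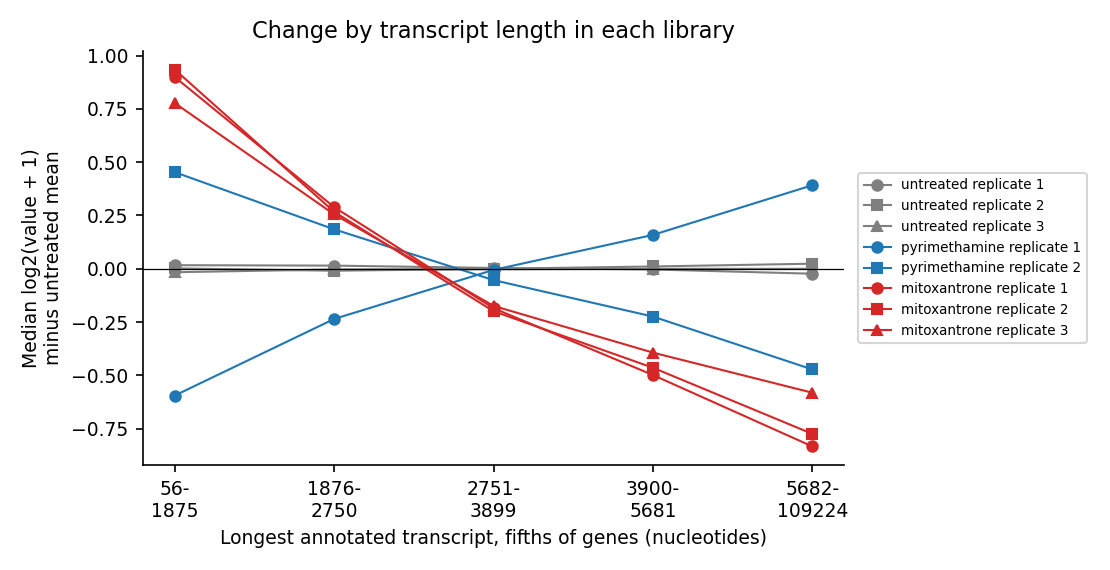
Median log2(value + 1) minus the untreated mean (y axis) for genes in 5 equal bins by longest annotated transcript in nucleotides (x axis), 1 line per library. In the shortest bin the medians were 0.90, 0.93 and 0.78 in the mitoxantrone libraries, 0.45 in pyrimethamine replicate 2 and -0.59 in pyrimethamine replicate 1, and the order was the opposite in the longest bin.

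The first comparison asked which genes pyrimethamine changed relative to untreated cells. Genes of NRF2-driven detoxification, of sterol synthesis and of fatty acid synthesis were lower, and interferon-stimulated, NF-kB, immediate early and secreted inflammatory genes were higher. These directions rest on camera with a preset correlation, and of its 18 list calls with pyrimethamine 1 held with an estimated correlation, that of the interferon-stimulated genes. Change also fell with untreated level, with rank correlations of -0.429 in replicate 1 and -0.219 in replicate 2. Of the lists just named, only NRF2 targets were compared with lists matched on level and length. The part of level in the others was not tested. LIPH, which encodes a phospholipase, rose from 23.3 ± 3.84 (SD, n = 3) to 306 and 287 in the 2 pyrimethamine libraries, a log2 fold change of 3.62 ± 0.22 (SE; limma, Benjamini-Hochberg adjusted p = 0.00221). SCD, the desaturase that makes monounsaturated fatty acids, fell from 26435 ± 138 to 8777 and 4684, a log2 fold change of -2.04 ± 0.28 (adjusted p = 0.0148). In all, 553 of 15350 genes passed the threshold, 352 higher and 201 lower, of which 315 and 128 changed at least 2-fold. The other highest log2 fold changes under the rule for named genes were 4.65 for PRR9, 3.69 for GPR1, 3.69 for MAP3K7CL, 3.44 for ODAPH and 3.25 for SPINK6. The mean of at least 100 was taken over all 8 libraries, so high values with mitoxantrone helped these genes to qualify. In that order, their untreated means were 3.40, 3.61, 8.57, 12.4 and 9.35, and their mitoxantrone means 472, 443, 598, 262 and 860. Among the other lowest were -2.54 for DHRS2, -2.25 for AKR1C2, -2.09 for DDIT4, a stress-induced inhibitor of mTORC1, and -2.04 for ID3. AKR1C2 is uncertain, since its reads can be shared with near-identical paralogs.

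The 2 pyrimethamine libraries departed from the untreated mean in different directions for most genes. Over the 15350 tested genes, 44.5% lay on the same side of the untreated mean in both libraries, and the deviations correlated at 0.123 across genes. All 553 called genes lay on the same side in both. The call itself nearly requires this, since libraries on opposite sides give a small mean change and a large spread. It is therefore no evidence of replication. The number of genes changed by pyrimethamine was 10 without untreated replicate 1, 10 without untreated replicate 2, 11 without untreated replicate 3, 83, 61 and 144 without mitoxantrone replicate 1, 2 and 3, 7276 without pyrimethamine replicate 1 and 7571 without pyrimethamine replicate 2. Fitted on these 2 groups alone with limma it was 0, with 2077 genes at an unadjusted p under 0.05, while edgeR and DESeq2 on the recovered reads of all libraries gave 670 and 1738. The split was 472 higher and 125 lower with upper-quartile scaling, and 786 higher and 930 lower after adjustment for transcript length and GC, an alternative chosen after the length trend was seen.

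Of 44 tested NRF2 targets, 6 fell with pyrimethamine and 0 rose, or 25 and 0 when adjusted over the list alone. The list median was -0.78 log2 units (camera adjusted p = 9.09e-11; adjusted p = 0.153 with an estimated correlation), with medians of -1.02 and -0.54 in replicates 1 and 2. SLC7A11, the cystine importer that feeds glutathione synthesis, fell from 4256 ± 118 (SD, n = 3) to 2124 and 1558, a log2 fold change of -1.23 ± 0.18 (adjusted p = 0.017). AKR1B10, an aldo-keto reductase, fell from 10994 ± 859 to 2042 and 4789, a log2 fold change of -1.81 ± 0.33 (adjusted p = 0.0282). OSGIN1 had a log2 fold change of -1.29 (adjusted p = 0.0168) and TKT, the transketolase of the pentose phosphate pathway, one of -1.27 (adjusted p = 0.0207). SRXN1, named after its value was seen to complete the 6 with AKR1C2, had -1.29 (adjusted p = 0.0213). NFE2L2 itself (chromosome 2, 177227595 to 177392697, GRCh38) had a log2 fold change of -0.44 ± 0.18 that missed the threshold (adjusted p = 0.216). The remaining genes of the pathway fixed for naming also missed it, with log2 fold changes of -0.08 for KEAP1, -0.78 for NQO1, -0.51 for GCLM, -0.75 for TXNRD1 and -0.23 for HMOX1. GCLC missed it narrowly, at 3763 and 2317 against 5901 ± 99.9 (adjusted p = 0.0552). NQO1, the quinone reductase, differed most between the libraries, at 7526 in replicate 1 and 24546 in replicate 2 beside 23306 ± 713 in untreated cells.

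**Figure D3:**
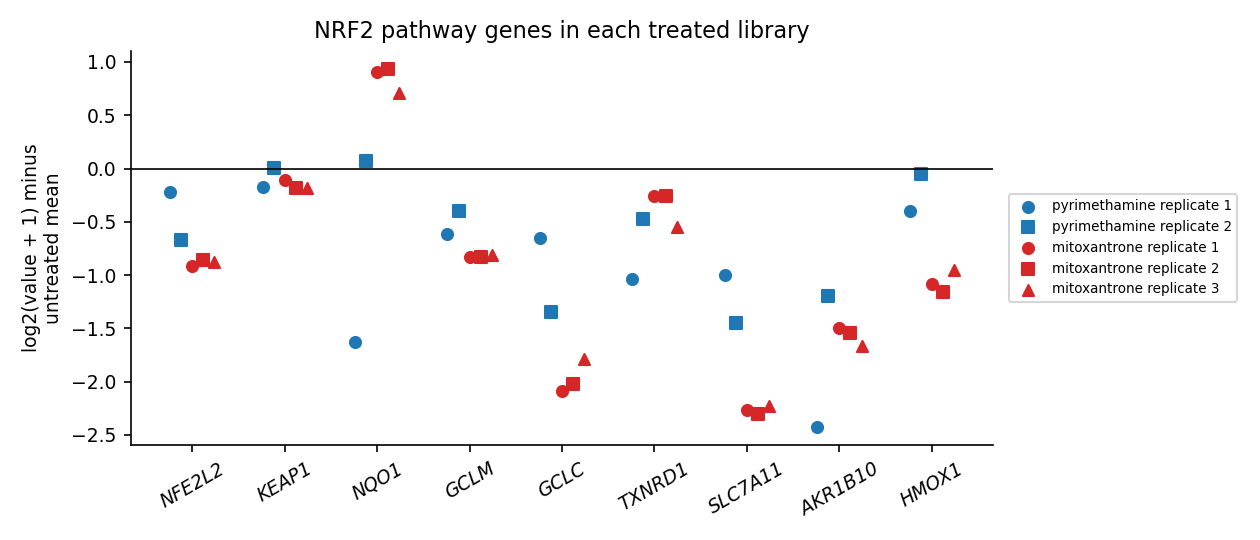
Log2(value + 1) minus the untreated mean (y axis) for 9 genes of the NRF2 pathway (x axis) in each of the 5 treated libraries, 1 point per library. SLC7A11 and AKR1B10 lie below the untreated mean in all 5 libraries, while NQO1 lies at 0.91, 0.94 and 0.71 in the mitoxantrone libraries, at -1.63 in pyrimethamine replicate 1 and at 0.08 in replicate 2.

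Lipid synthesis genes were lower with pyrimethamine as well. Of 25 cholesterol synthesis genes 5 fell (12 when adjusted over the list alone) and 0 rose, with a median of -0.78 (camera adjusted p = 1.54e-08; adjusted p = 0.153 with an estimated correlation). Among them, log2 fold changes were -1.11 for HMGCS1, the synthase upstream of HMG-CoA reductase, -0.97 for DHCR7 and -1.31 for the mevalonate kinase gene MVK. Of 16 fatty acid synthesis genes 4 fell (9 when adjusted over the list alone), with a median of -0.81 (camera adjusted p = 9.74e-07; adjusted p = 0.153 with an estimated correlation). Besides SCD these included FADS2 at -1.35 and SREBF1, the transcription factor that drives lipogenic genes, at -1.97, from 4914 ± 245 (SD, n = 3) to 1831 and 856.

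Immune and stress-signalling lists were higher. Of 32 interferon-stimulated genes 5 rose (16 when adjusted over the list alone) and 0 fell, with a median of 0.99 (camera adjusted p = 1.99e-11), and this was the 1 list called with an estimated correlation (adjusted p = 0.0397). IFI6 rose from 57.3 ± 3.61 (SD, n = 3) to 182 and 299, and HERC6 and OAS1 had log2 fold changes of 1.52 and 1.76. Of 24 NF-kB and cytokine genes 6 rose (11 over the list alone), with a median of 0.84 (adjusted p = 2.26e-06; adjusted p = 0.0797 with an estimated correlation), among them SAA1 at 2.91, RELB at 1.69 and TNFRSF9 at 2.61. Of 27 immediate early and AP-1 genes 10 rose, or 15 higher and 1 lower over the list alone, with a median of 0.62 (adjusted p = 8.73e-09; adjusted p = 0.153 with an estimated correlation). They included the phosphatases DUSP5 at 1.41 and DUSP4 (adjusted p = 0.0122), both induced by ERK signalling, and FOSB at 2.91. Of 24 genes of senescence-associated secretion 4 rose (7 over the list alone), with a median of 0.74 (adjusted p = 1.45e-06; adjusted p = 0.0797 with an estimated correlation), including ANGPTL4 at 2.88, the EGFR ligand AREG at 1.28 and GDF15, at 1301 and 1235 against 588 ± 91.8. Of 16 genes of MHC class I and antigen processing 3 rose (6 over the list alone), with a median of 0.77 (adjusted p = 2.17e-05; adjusted p = 0.106 with an estimated correlation). These were HLA-B at 1.74, CD274 at 1.60 and HLA-E at 0.82, and reads of the HLA genes can be shared among family members.

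A further 10 lists passed camera with pyrimethamine, and each lost its call or turned direction under at least 1 of 21 alternatives. Ribosomal protein genes had 0 of 71 called, a median of -0.74 (adjusted p = 3.22e-05; adjusted p = 0.717 with an estimated correlation) and library medians of -1.88 and 0.44. Nuclear oxidative phosphorylation genes had 0 of 44 called and a median of -0.37 (adjusted p = 0.0329; adjusted p = 0.814 with an estimated correlation). In the fit without pyrimethamine replicate 1 the cytosolic ribosomal proteins (adjusted p = 1.97e-10) and nuclear oxidative phosphorylation genes (adjusted p = 1.66e-10) were called higher instead. For G2/M and mitosis, 1 of 39 genes fell, the kinase gene PLK1 at -1.08, with a list median of -0.37 (adjusted p = 0.00407; adjusted p = 0.153 with an estimated correlation). The heat shock response list had a median of -0.52 (adjusted p = 0.00347; adjusted p = 0.153 with an estimated correlation), with HSPA1B lower at -1.61, a gene that shares reads with HSPA1A, and the small chaperone gene CRYAB higher at 1.80. The list of MYC targets and ribosome biogenesis had 1 of 37 lower, BOP1 at -0.88, and a median of -0.28 (adjusted p = 0.012; adjusted p = 0.153 with an estimated correlation). Purine and pyrimidine synthesis had 0 of 27 called and a median of -0.30 (adjusted p = 0.012; adjusted p = 0.622 with an estimated correlation). Aldehyde dehydrogenases and P450s had 2 of 17 lower, ALDH3A2 at -1.35 and ALDH3B1 at -0.81, and a median of -0.62 (adjusted p = 0.0362; adjusted p = 0.271 with an estimated correlation).

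Squamous differentiation genes had 4 of 26 higher and 2 lower and a median of 0.47 (adjusted p = 0.0207; adjusted p = 0.162 with an estimated correlation). KLK5, ECM1 and KRT4 had log2 fold changes of 1.81, 1.73 and 1.91. Mesenchymal transition genes (0 of 25 called, median 0.47, adjusted p = 0.0243; adjusted p = 0.168 with an estimated correlation) and fibroblast markers (0 of 9 called, median 0.54, adjusted p = 0.0182; adjusted p = 0.173 with an estimated correlation) also passed camera. In the fit without pyrimethamine replicate 1 the calls of the mesenchymal transition, fibroblast markers, squamous differentiation and purine and pyrimidine synthesis lists were lost (adjusted p = 0.609, 0.205, 0.393 and 0.487). In the fit without pyrimethamine replicate 2 those of the G2/M and mitosis, MYC targets and ribosome biogenesis, aldehyde dehydrogenases and P450s, squamous differentiation and fibroblast markers lists were lost (adjusted p = 0.428, 0.469, 0.428, 0.0825 and 0.0527). Without untreated replicate 1 that of the aldehyde dehydrogenase and P450 list was also lost. The heat shock call was lost with quantile normalisation and cyclic loess, and the oxidative phosphorylation call with a mean of at least 50 and cyclic loess.

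TYMS, thymidylate synthase, did not pass the threshold with pyrimethamine, with a log2 fold change of -0.21 (adjusted p = 0.832), and neither did the topoisomerase genes. TOP2A stood at 5082 in replicate 1 and 1015 in replicate 2 beside 2384 ± 147 (SD, n = 3) untreated, and TOP2B at 1414 and 258 beside 1211 ± 87.3. Of the p53 targets, CDKN1A had 0.08 and MDM2 -0.66, both short of the threshold, while 3 of 37 list members rose and 1 fell (camera adjusted p = 0.505). Those 4, named after their values were seen, were TP53I3 at 2.11, FAS at 2.04 and GDF15 higher and TP53INP1 lower.

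The second comparison asked which genes mitoxantrone changed. Of 15350 genes 8430 passed the threshold, 4119 higher and 4311 lower, of which 3168 and 2978 changed at least 2-fold. Short, abundant transcripts of the ribosome and of oxidative phosphorylation, histone genes and interferon-stimulated genes were higher, and NRF2 targets, lipid synthesis genes and basal squamous genes were lower. These directions rest on camera with a preset correlation, and of its 15 list calls with mitoxantrone 0 held with an estimated correlation. The estimate includes the pyrimethamine pair, whose libraries stood 2.32 log2 units apart for ribosomal protein genes. It therefore cannot separate spread within the untreated and mitoxantrone groups from that of the pyrimethamine pair. Change with mitoxantrone also fell with untreated level, with rank correlations of -0.188 to -0.206. Of the lists just named, only NRF2 targets, ribosomal protein and oxidative phosphorylation genes were compared with lists matched on level and length. DHRS2, a short-chain dehydrogenase gene (chromosome 14, 23630115 to 23645639), fell from 403 ± 7.92 (SD, n = 3) to 6.41 ± 1.18 (n = 3), a log2 fold change of -5.78 ± 0.27 (SE; limma adjusted p = 6.91e-05). SREBF1 (chromosome 17, 17810399 to 17837002) fell from 4914 ± 245 to 260 ± 64.4, a log2 fold change of -4.26 ± 0.30 (adjusted p = 1.65e-04). SAA1, an acute-phase gene with a near-identical paralog, rose from 61.2 ± 5.08 to 2345 ± 77.8, a log2 fold change of 5.24 ± 0.30 (adjusted p = 1.18e-04). PRR9, GPR1, SPINK6 and MAP3K7CL, all under 10 in untreated cells on average, had log2 fold changes of 6.89, 6.66, 6.44 and 6.42, and the histone gene H2BC11 had 4.70. Among the lowest were PALM3 at -3.97, the cadherin gene CDH4 at -3.93, SCD at -3.74 and GNAZ at -3.66. With upper-quartile scaling the split of genes changed by mitoxantrone was 5642 higher and 2998 lower, with the median of all genes at 0.34.

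Of 44 NRF2 targets 24 fell with mitoxantrone and 3 rose, with the same counts over the list alone. The median was -0.80 (camera adjusted p = 5.01e-04; adjusted p = 0.392 with an estimated correlation), and the 3 libraries had medians of -0.75, -0.83 and -0.82. NFE2L2 fell from 1382 ± 46.2 (SD, n = 3) to 750 ± 14.1, a log2 fold change of -0.88 ± 0.16 (adjusted p = 0.0031). SLC7A11 fell to 882 ± 21.7, a log2 fold change of -2.27 ± 0.16 (adjusted p = 1.68e-04), and OSGIN1 and the P450 gene CYP4F11 fell with log2 fold changes of -2.27 and -2.71. The glutamate-cysteine ligase genes GCLC and GCLM had -1.96 and -0.82, AKR1B10 -1.57 and HMOX1, heme oxygenase, -1.06, all past the threshold. KEAP1 (-0.16, adjusted p = 0.358) and TXNRD1 (-0.35, adjusted p = 0.246) did not pass it. NQO1 stood at 42161 ± 3509 against 23306 ± 713, a log2 fold change of 0.85 ± 0.41 with adjusted p = 0.108. Its mitoxantrone values of 43721, 44620 and 38143 all lay above the untreated ones of 24090.5, 22699 and 23127. The standard error rests on a spread shared with the pyrimethamine libraries, at 7526 and 24546. The 3 members that rose, named after their values were seen, were GSTM3 at 2.62, UCHL1 at 1.20 and BLVRB at 1.26.

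Lipid synthesis genes were lower with mitoxantrone too. Of 16 fatty acid synthesis genes 14 fell and 0 rose, with a median of -1.18 (camera adjusted p = 3.72e-05; adjusted p = 0.153 with an estimated correlation), and FADS2 had -2.76. Of 25 cholesterol synthesis genes 12 fell and 2 rose, with a median of -0.39 (adjusted p = 0.0127; adjusted p = 0.425 with an estimated correlation). DHCR7, HMGCS1 and the lanosterol synthase gene LSS had -1.80, -1.75 and -2.10.

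Ribosomal protein genes had 23 of 71 higher and 0 lower, but 0 when adjusted over the list alone, with a median of 1.31 (camera adjusted p = 1.83e-06; adjusted p = 0.671 with an estimated correlation). RPL11 rose from 13081 ± 850 (SD, n = 3) to 39871 ± 4363, and RPS27 and RPL12 had log2 fold changes of 1.90 and 1.63. Nuclear oxidative phosphorylation genes had 28 of 44 higher and 1 lower (33 and 1 over the list alone), with a median of 1.40 (adjusted p = 1.96e-05; adjusted p = 0.644 with an estimated correlation), among them COX6C at 2.26, UQCRB at 1.66 and NDUFB3 at 2.12. The 1 lower member, named after its value was seen, was SDHA at -0.52. After adjustment of each library for transcript length and GC the medians were 0.40 and 0.50. Of 18 replication-dependent histone genes 14 rose and 2 fell, with a median of 2.72 (adjusted p = 4.3e-05; adjusted p = 0.457 with an estimated correlation). H2AC11, H2BC5 and H2BC4 had 3.14, 3.02 and 4.26, and histone genes can share reads with near-identical copies.

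Interferon-stimulated genes had 15 of 32 higher and 3 lower, with a median of 0.75 (camera adjusted p = 0.00352; adjusted p = 0.153 with an estimated correlation). IFI6 rose to 714 ± 53.9 (SD, n = 3), ISG20 and IFIT1 had 3.99 and 1.80, and MX1, named after its value was seen, had -1.81. MHC class I and antigen processing genes had 10 of 16 higher and 3 lower, with a median of 1.15 (adjusted p = 0.0267; adjusted p = 0.197 with an estimated correlation), and HLA-B and HLA-C had 2.67 and 1.19. Senescence-associated secretion had 12 of 24 higher and 2 lower (14 and 2 over the list alone), with a median of 1.29 (adjusted p = 0.00972; adjusted p = 0.153 with an estimated correlation). AREG, GDF15 and IL1B had 2.82, 1.75 and 1.74. NF-kB and cytokine genes, with 9 of 24 higher and 7 lower, and immediate early genes, with 12 of 27 higher and 6 lower, did not pass camera (adjusted p = 0.169 and 0.079), although the immediate early list was called in 5 of 21 alternatives.

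Basal squamous cell genes had 11 of 24 lower and 0 higher, with a median of -0.88 (camera adjusted p = 0.00273; adjusted p = 0.614 with an estimated correlation; adjusted p = 0.0534 after adjustment for transcript length and GC). TP63, the master regulator of squamous basal cells, fell from 3349 ± 56.6 (SD, n = 3) to 891 ± 58.8, SOX2 had a log2 fold change of -2.51, and the integrin gene ITGB4 had -2.21. Of 7 glandular epithelium markers 5 rose, with a median of 0.98 (adjusted p = 0.035; adjusted p = 0.494 with an estimated correlation), including AGR2 at 3.05, MUC1 at 2.40 and the simple-epithelial keratin gene KRT18 at 0.98. The AGR2 level was 41.1 ± 9.30 against 4.35 ± 2.52. This call was lost under 8 of the 20 alternatives in which the list could be tested, including those without untreated replicate 2 and without pyrimethamine replicate 2.

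In the unfolded protein response 12 of 23 genes fell and 3 rose with mitoxantrone, with a median of -0.45 (camera adjusted p = 0.0248; adjusted p = 0.366 with an estimated correlation), including SEC24D at -1.81, HYOU1 at -1.94 and HSPA5, the main chaperone of the endoplasmic reticulum, at -1.37. In the ATF4 and amino acid response list 16 of 33 fell and 4 rose (17 and 4 over the list alone), with a median of -0.47 (adjusted p = 0.0362; adjusted p = 0.366 with an estimated correlation). SLC7A11, which belongs to this list too, and DDIT4 at -2.82 were lower, and ATF3 at 2.21 was higher. The MYC target and ribosome biogenesis list had 18 of 37 lower and 3 higher (18 and 4 over the list alone), with a median of -0.44 (adjusted p = 0.0171; adjusted p = 0.155 with an estimated correlation), and BOP1, NAT10 and CAD had -1.33, -1.80 and -1.80. Aldehyde dehydrogenases and P450s had 10 of 17 lower and 1 higher, with a median of -0.65 (adjusted p = 0.0329; adjusted p = 0.261 with an estimated correlation). CYP4F11 and ALDH3B1 (-1.51) were lower and TIPARP (1.56) was higher. The ATF4 call was lost without untreated replicate 2, with a mean of at least 50, with upper-quartile scaling and with replicate numbers as a block. The aldehyde dehydrogenase and P450 call was lost without untreated replicate 1 and with a mean of at least 50, the MYC target call with a mean of at least 50 and upper-quartile scaling, and the unfolded protein response call with a mean of at least 50. The MHC class I call was lost without pyrimethamine replicate 2, with upper-quartile scaling and in a fit of only the 2 groups.

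TOP2B, a target of mitoxantrone, fell from 1211 ± 87.3 (SD, n = 3) to 175 ± 51.6, a log2 fold change of -2.82 ± 0.54 (adjusted p = 0.00387). TOP2A had -0.93 ± 0.49 (adjusted p = 0.136). CDKN1A at 0.39 (adjusted p = 0.122), MDM2 at -0.39 (adjusted p = 0.0707) and TYMS at 0.42 (adjusted p = 0.364) did not pass. The spread behind these p-values is shared with the pyrimethamine libraries. Of all genes taken by the naming rule, 7 that missed the threshold with mitoxantrone passed it in a fit of only the 2 groups. Of 37 p53 targets 9 rose and 5 fell (camera adjusted p = 0.249). Cell-cycle lists moved in both directions, with 11 of 39 G2/M and mitosis genes higher and 6 lower (adjusted p = 0.629) and 10 of 49 S phase genes higher and 20 lower (adjusted p = 0.52).

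The third comparison asked where the compounds differed. Their doses differ by design, and they are not structural analogs. Mitoxantrone and pyrimethamine differed in 6299 of 15350 genes, 3247 higher and 3052 lower with mitoxantrone. Ribosomal protein genes were higher with mitoxantrone for 65 of 71 members (70 over the list alone), with a median difference of 2.01 (camera adjusted p = 5.91e-13; adjusted p = 0.558 with an estimated correlation). RPL11, RPS12 and RPL17 differed by 1.96, 2.77 and 2.29, the last with reads that overlapping genes can share. Oxidative phosphorylation genes were higher for 35 of 44 (41 higher and 1 lower over the list alone), with a median of 1.70 (adjusted p = 5.16e-09; adjusted p = 0.558 with an estimated correlation), and COX6C, UQCRB and NDUFB3 differed by 2.16, 1.66 and 2.22. Histone genes were higher for 16 of 18, with a median of 2.58 (adjusted p = 3.05e-08; adjusted p = 0.334 with an estimated correlation), and H2AC11, H2BC5 and H2BC4 differed by 2.98, 2.46 and 3.23. Basal squamous genes were lower for 10 of 24, with a median of -0.96 (adjusted p = 8.32e-04; adjusted p = 0.583 with an estimated correlation), with TP63, SOX2 and ITGB4 at -1.51, -1.32 and -1.73. Fatty acid synthesis genes were lower for 8 of 16 (9 over the list alone), with a median of -0.73 (adjusted p = 0.011; adjusted p = 0.33 with an estimated correlation), with SREBF1, FADS2 and SCD at -2.29, -1.41 and -1.70.

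G2/M and mitosis genes were higher with mitoxantrone than with pyrimethamine for 18 of 39 and lower for 1, with a median of 0.35 (camera adjusted p = 0.0267; adjusted p = 0.162 with an estimated correlation), and NEK2, UBE2C and CDC25C differed by 1.69, 1.55 and 1.40. ATF4 and amino acid response genes were lower for 13 of 33 and higher for 2 (14 and 2 over the list alone), with a median of -0.47 (adjusted p = 0.0326; adjusted p = 0.366 with an estimated correlation), with NUPR1, SLC7A11 and SLC7A1 at -1.43, -1.04 and -1.53. Glandular epithelium markers were higher for 4 of 7 (5 over the list alone), with a median of 0.70 (adjusted p = 0.0326; adjusted p = 0.494 with an estimated correlation), with AGR2 at 2.71, KRT7 at 1.69 and KRT18 also higher (adjusted p = 0.0199). In the fit without pyrimethamine replicate 2 the calls of the G2/M and mitosis, ATF4 and amino acid response and glandular epithelium markers lists were lost (adjusted p = 0.602, 0.167 and 0.0747). Quantile normalisation and cyclic loess also ended the G2/M and glandular calls, no filter and adjustment for length and GC the glandular call, and upper-quartile scaling and the title-number block the ATF4 call.

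Of NRF2 targets, 6 of 44 were higher with mitoxantrone and 14 were lower than with pyrimethamine, and the list did not pass camera (adjusted p = 0.693), with a median of 0.12 and a mean of 0.06 although the sign of the camera test was negative. It was called lower with mitoxantrone in 3 of 21 alternatives, namely quantile normalisation (adjusted p = 0.00862 for NRF2 targets), cyclic loess between libraries (adjusted p = 2.44e-04) and the fit without pyrimethamine replicate 1 (adjusted p = 0.043). SLC7A11 was lower with mitoxantrone than with pyrimethamine (adjusted p = 0.0177). GCLC at -0.96 (adjusted p = 0.0241), HMOX1 at -0.84 (adjusted p = 0.0207) and NQO1 at 1.63 (adjusted p = 0.0301), named here after their values were seen, also differed. NFE2L2 did not pass (-0.44 ± 0.18, adjusted p = 0.0731). Among called genes with a mean of at least 100, no overlap between the libraries and no clone symbol, the 4 highest differences were 3.74 for MYL2, 3.51 for the small nuclear RNA gene RN7SK, 3.40 for H2BC11 and 3.23 for H2BC4, and the 4 lowest were -3.24 for DHRS2, -3.06 for PALM3, -2.88 for SDK2 and -2.88 for EGFR-AS1, an antisense gene whose reads cannot be told from those of EGFR without strand. The number of genes differing between mitoxantrone and pyrimethamine was 0 without mitoxantrone replicate 1 (6383 at an unadjusted p under 0.05) and 2 without mitoxantrone replicate 2, 2568 without mitoxantrone replicate 3, 2466, 2136 and 2169 without untreated replicate 1, 2 and 3, and 11638 without pyrimethamine replicate 2. The split was 4103 higher and 2095 lower with upper-quartile scaling, and 2512 higher and 4201 lower of 6713 with edgeR on the recovered reads.

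**Figure D4:**
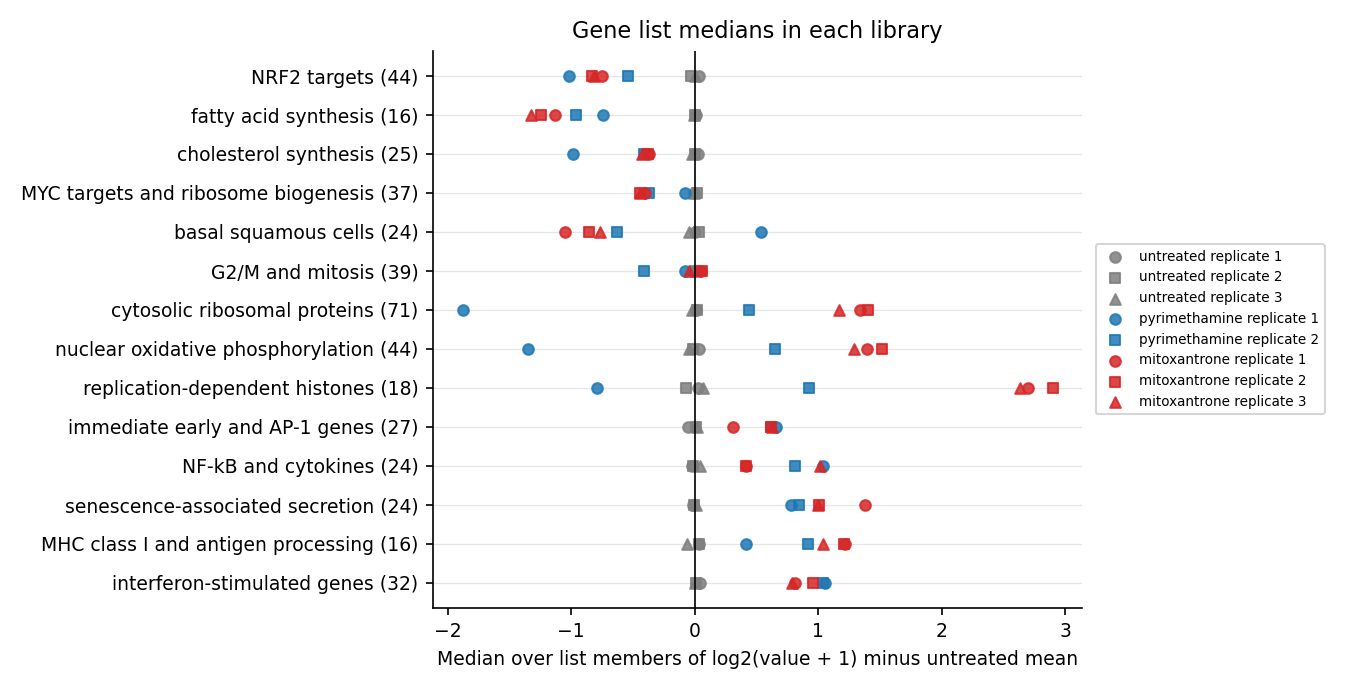
Median over the tested members of 14 gene lists of log2(value + 1) minus the untreated mean (x axis), 1 point per library, with the number of members in brackets. NRF2 targets and fatty acid synthesis genes lie below the untreated mean in all 5 treated libraries and interferon-stimulated genes above it, while ribosomal protein medians are -1.88 and 0.44 in the pyrimethamine libraries and 1.34, 1.40 and 1.17 in the mitoxantrone libraries.

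Genes changed by both compounds in the same direction numbered 507, 326 higher and 181 lower, which is 91.7% of the 553 called with pyrimethamine. Independent lists of the same sizes would share 94.5 higher and 56.5 lower. In 50 simulations of unchanged groups that shared 3 simulated untreated libraries, 0 genes were called alike in both on average. With no gene changed, few calls can arise in either comparison. That 0 therefore does not show how much overlap shared controls give. The fold changes correlated at 0.544 across genes beside 0.170 in the simulations, and their covariance was 0.501 beside 0.0293, a difference of 0.472. With 3 untreated libraries the controls cannot be split, and part of the excess may come from the shared controls. The correlation with the mitoxantrone mean was 0.852 for pyrimethamine replicate 2 alone and -0.012 for replicate 1 alone. In all 553 calls both pyrimethamine libraries lay on the same side, so each call had the sign of replicate 2. Agreement in direction with mitoxantrone is thus partly built in by the call. Independent lists are therefore too low a baseline, and 91.7% does not measure a shared response. Of the 507 genes 363 changed more with mitoxantrone, and for 174 the difference between compounds passed the threshold. The number of genes changed by both compounds was 10, 10 and 11 without untreated replicate 1, 2 and 3, 80, 59 and 135 without mitoxantrone replicate 1, 2 and 3, 6834 without pyrimethamine replicate 1 and 1960 without pyrimethamine replicate 2.

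In opposite directions 4 genes changed, named after their values were seen. TXNIP, an inhibitor of thioredoxin and of glucose uptake, fell with pyrimethamine from 2416 ± 127 (SD, n = 3) to 566 and 781 and rose with mitoxantrone to 4268 ± 99.8 (n = 3). The log2 fold changes were -1.86 ± 0.18 (adjusted p = 0.009) and 0.82 ± 0.17 (adjusted p = 0.00486), and the compounds differed by 2.68 (adjusted p = 0.00277). PTGS2, the inducible cyclooxygenase gene, had 0.97 with pyrimethamine (adjusted p = 0.0292) and -0.43 with mitoxantrone (adjusted p = 0.0471). FAM72B had -0.96 and 0.83, and PLS3-AS1, an antisense gene whose reads cannot be told from those of its partner without strand, had -1.58 and 1.08.

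Further fixed lists passed camera in neither comparison with untreated cells. With pyrimethamine and mitoxantrone, the adjusted p was 0.169 and 0.629 for folate and one-carbon metabolism (1 of 24 lower, then 4 higher and 7 lower), 0.249 and 0.588 for glycolysis and hypoxia (1 of 29 lower, then 4 higher and 10 lower), and 0.974 and 0.511 for STAT3 targets (0 of 18, then 2 higher and 6 lower). It was 0.445 and 0.278 for YAP/TAZ targets (2 of 23 higher and 1 lower, then 6 higher and 12 lower), 0.353 and 0.687 for lysosome and autophagy (0 of 30, then 9 higher and 8 lower), 0.845 and 0.0959 for double-strand break repair (1 of 30 lower, then 5 higher and 14 lower), and 0.384 and 0.457 for ABC drug transporters (0 of 9, then 2 higher and 3 lower). Of the lists called with mitoxantrone, those not called with pyrimethamine had an adjusted p of 0.86 for histones (2 of 18 lower), 0.505 for basal squamous cells (1 of 24 lower), 0.079 for the unfolded protein response (0 of 23), 0.52 for ATF4 and amino acid response (2 of 33 higher and 3 lower) and 0.914 for glandular epithelium markers (1 of 7 higher). Basal squamous cells were called lower with pyrimethamine in the fit without pyrimethamine replicate 1 (adjusted p = 9.75e-06) and higher in the fit without pyrimethamine replicate 2 (adjusted p = 0.0128). S phase genes had 0 of 49 called (adjusted p = 0.959). Besides the G2/M and mitosis, NF-kB and immediate early lists given above, further lists called with pyrimethamine were not called with mitoxantrone. Their adjusted p with mitoxantrone was 0.078 for the heat shock response (1 of 21 higher and 10 lower, called lower in 5 of 21 alternatives), 0.86 for purine and pyrimidine synthesis (7 of 27 higher and 6 lower), 0.214 for squamous differentiation (9 of 26 higher and 4 lower), 0.959 for mesenchymal transition (7 of 25 higher and 4 lower) and 0.52 for fibroblast markers (3 of 9 higher and 4 lower). The smallest adjusted p of the uncalled lists between the compounds was 0.0709, for YAP/TAZ targets. Too few members were tested of metallothionein genes (4, all 4 higher with mitoxantrone), endothelial markers (3) and leukocyte markers (1). For mitochondrially encoded mRNAs no member was analysed here.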

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

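The adjustments for transcript length and GC and the test for mixed RNA were chosen after the results were seen, and the others before. The interval used for nuclear-retained RNAs was also added after its value was seen.

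In 4 gene lists the compounds' effects differed by a direct test while their medians against untreated cells lay on opposite sides of 0. The median difference, mitoxantrone minus pyrimethamine, was 2.01 log2 units for cytosolic ribosomal proteins, 1.70 for nuclear oxidative phosphorylation, 0.35 for G2/M and mitosis and 0.70 for glandular epithelium markers. With an estimated correlation the adjusted p was 0.558, 0.558, 0.162 and 0.494, so none of these 4 calls held there. In the fit without pyrimethamine replicate 2 the calls of the G2/M and mitosis list (adjusted p = 0.602) and of the glandular epithelium markers (adjusted p = 0.0747) were lost, as they were with quantile normalisation and cyclic loess, and the glandular call also with no filter and after adjustment for length and GC.

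For ribosomal proteins, the pyrimethamine libraries themselves stood 2.32 log2 units apart. Length and GC trends do not account for all of this, since 1.44 units remained after each library was adjusted for them. The change also followed untreated level, with rank correlations of -0.429 in replicate 1 and -0.219 in replicate 2. Lists matched on level and length had medians of -1.08 and 0.29 there, beside -1.88 and 0.44 for ribosomal proteins (percentiles 0 and 98.97). Level and length therefore go with much of the gap, but not with all of it. Replicate 2 as mitoxantrone RNA, or a mixture of it with untreated RNA, is argued against by the mixing share, which was 0.329 from raised genes and 0.768 from lowered genes, a difference of 0.439 (bootstrap interval 0.414 to 0.460). More nuclear RNA in replicate 1 stays open. Of 9 nuclear-retained RNAs 4 were higher and 5 lower there, with a median of -0.68 log2 units at percentile 1.16 of lists of like level. The bound written before the test counts a percentile this low against the explanation. The interval of that median (-0.91 to 1.69) was made a further condition after the value was seen, and only this left the question open. MALAT1 (1.80) and NEAT1 (1.30), left out because their values had been seen, were higher. A true difference in exposure, RNA quality or library preparation between the replicates was not tested and may underlie the pattern.

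Ribosomal protein and oxidative phosphorylation genes were higher with mitoxantrone, and the length trend is part of that pattern: adjustment for length and GC took the ribosomal protein median from 1.31 to 0.40 and that of oxidative phosphorylation from 1.40 to 0.50. The value of 0.403 lies under the bound of 0.5 log2 units first written for this test; another bound tried after the value was seen gave the other verdict and is not used. Length and GC trends may therefore account for the pattern, and although the list still passed camera at the preset correlation (adjusted p = 0.00924 for cytosolic ribosomal proteins, adjusted for transcript length and GC), the call on deposited values did not hold with an estimated correlation (adjusted p = 0.671). Lists matched on untreated level and length, but not on GC, had a median of 0.68 (interval 0.42 to 0.98). The ribosomal protein list lay at percentile 100 of them, so level and length alone do not give its full size. Whether the trend comes from the compound or from RNA integrity stays open, because treatment and any handling difference coincide.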

How the results depend on the processing

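Adjustment for transcript length and GC and cyclic loess were chosen after the results were seen, the other alternatives before. The count of genes changed by mitoxantrone stayed within 1.5 times of 8430 in all alternatives (5687 to 11841), while those involving pyrimethamine did not.

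In number, genes changed by pyrimethamine (553) numbered 291 with no filter, 322 with quantile normalisation, 1738 with DESeq2, 1716 adjusted for length and GC, and 10 to 7571 with 1 library left out. Likewise, genes differing between mitoxantrone and pyrimethamine (6299) numbered 3715 adjusted for length and GC and 0 to 11638 with 1 library left out. Finally, genes changed by both compounds (507) numbered 267 with no filter, 300 with quantile normalisation, 1399 with DESeq2, 1512 adjusted for length and GC, and 10 to 6834 with 1 library left out. Fitting only the 2 groups compared gave 0 for all 3 with limma (2077 and 6009 genes at an unadjusted p under 0.05 for pyrimethamine and between compounds). That fit leaves the pyrimethamine libraries to set much of the spread. The main fit instead assumes an equal spread in all groups. The chi-square per degree of freedom goes against this, at 394 between the pyrimethamine libraries and 3.54 to 13.4 within the other groups. P-values of the main fit that involve pyrimethamine may therefore be too small. The causes of the other shifts were not tested. A lone pyrimethamine library was assumed to vary like the other groups.

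With replicate numbers as a block, genes changed by pyrimethamine, genes differing between mitoxantrone and pyrimethamine and genes changed by both compounds numbered 0 with title numbers (2084 and 7359 at an unadjusted p under 0.05 for the first and second) and 0 with description numbers (2027 and 6499), and genes changed by mitoxantrone 7251 and 6592. Same-numbered untreated and mitoxantrone libraries had residual correlations of 0.0526, -0.00784 and 0.0183, which gave no sign of pairing. Pyrimethamine replicate 1 had -0.287 with mitoxantrone replicate 1. Pyrimethamine replicate 2 had 0.127 with its mitoxantrone match by title number and -0.41 by description number. With so few libraries, these values cannot show whether the numbers mark shared cultures or days.

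The gene lists changed by pyrimethamine and gene lists changed by mitoxantrone, 18 and 15, fell to 1 and 0 with an estimated correlation, and gene lists differing between mitoxantrone and pyrimethamine from 8 to 0. With fry the mitoxantrone lists numbered 23 and the differing lists 16; the latter were 14 with no filter and 13 with cyclic loess. In all 21 alternatives to the camera fit, NRF2 targets, cholesterol and fatty acid synthesis, interferon-stimulated genes and senescence-associated secretion were called in the same direction with both compounds.

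Reversal was examined for the named genes only. Those reversed past the threshold were TYMS with pyrimethamine (0.36 without pyrimethamine replicate 1) and with mitoxantrone (-0.46 with quantile normalisation, -0.79 with cyclic loess), TOP2A with pyrimethamine (1.09 without pyrimethamine replicate 2, -1.23 without pyrimethamine replicate 1) and CDKN1A with pyrimethamine (-0.25 and 0.42 in the same order). The cause was not tested. Of the named genes called with pyrimethamine, nearly all lost their call (44, 44 and 43) without untreated replicate 1, 2 and 3. The median of all genes moved by 0.34 (mitoxantrone) and 0.20 (between compounds) with upper-quartile scaling, by -0.11 and -0.15 with TMM, and by -0.12 between compounds with edgeR. Depth limits low genes, and at 2-fold few simulated changes were recovered. That simulation changed 200 genes, so its share does not carry over to mitoxantrone, where 8430 genes passed.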

Other observations

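The tests on NRF2 targets, on other splits of the libraries and on gene span were set before their results were seen, and the genes named in the next 2 paragraphs were chosen after their values were seen. Values of these genes were not adjusted for transcript length. Change with mitoxantrone followed that length, with rank correlations of -0.418 to -0.396, and its part in these genes was not tested.

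ABCG2, an exporter for which mitoxantrone is a substrate, rose from 350 ± 12.1 (SD, n = 3) to 1966 ± 248 (n = 3), a log2 fold change of 2.48 ± 0.25 (limma adjusted p = 4.52e-04), and stood at 437 and 880 with pyrimethamine (adjusted p = 0.153). ABCC1, an exporter that is also an NRF2 target, fell from 3495 ± 180 to 497 ± 149 (adjusted p = 0.0011). The metallothionein genes MT2A, MT1X and MT1F rose with log2 fold changes of 1.88, 2.25 and 2.11 and the zinc exporter gene SLC30A1 with 0.84. B2M, the light chain of MHC class I, rose from 6278 ± 193 to 43372 ± 3669, and stood at 5836 and 19466 in the pyrimethamine libraries.

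Within the cell cycle, CDK1 rose with mitoxantrone from 7070 ± 314 (SD, n = 3) to 33051 ± 2741 (n = 3), while MKI67 and FOXM1 fell, with log2 fold changes of -1.71 and -1.60 (adjusted p = 0.0321 and 0.00251). ANKRD1, a YAP/TAZ target, rose with both compounds, by 2.31 with pyrimethamine (9284 and 5056 against 1378 ± 87.6) and 2.35 with mitoxantrone.

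The lower NRF2 targets were weighed against the level and length of those genes. In each of the 5 treated libraries the list median was set among 10000 lists matched on untreated level and transcript length, and the highest percentile was 0.19. Without the 10 members that fell most, the rest lay at percentile 0 of lists trimmed alike with both compounds, with medians of -0.71 (pyrimethamine) and -0.51 (mitoxantrone) beside -0.23 and 0.56 for the trimmed lists. In pyrimethamine replicate 1 the matched lists had a median of -0.66 beside -1.02 for the NRF2 targets, so level and length go with much of the size in that library. They do not account for the whole pattern, nor do a few members, and a lower output of NRF2 itself may contribute; protein levels were not analysed here, and general toxicity of the compounds was not tested.

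Long genes were lower with mitoxantrone, and a hypothesis was that the span of the gene in the genome, over which a topoisomerase poison could block transcription, sets the change. Given transcript length, GC and level, the rank correlation of the change with the span was -0.0405 to -0.0444 in the 3 mitoxantrone libraries, against -0.441 to -0.400 for transcript length given the span. The span is therefore not the property that the change follows.

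With 3 libraries against 3, other splits are too few for a share under 0.05. Of the 10 splits of the untreated and mitoxantrone libraries, 1 called as many genes as the real one, namely the real split itself, with 8430, and the highest other called 0. Every other split mixes untreated and mitoxantrone libraries on both sides, which widens the spread within each side. So few calls could arise there, and the contrast with 8430 lends no support.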
